A study of Mus musculus with 9 samples.

How the data were processed

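Poly-A RNA was sequenced from 3 mouse lung squamous cell carcinoma lines, JH716-18, LN1A and LN2A, with 3 libraries each. Per the labels' protocols, RNA was isolated with a Zymo Quick-RNA MicroPrep kit, quantified by Qubit, and made into libraries with the Illumina TruSeq Stranded mRNA kit. The authors deposited 1 table of estimated counts per gene symbol, for 55291 symbols and 9 libraries, not normalised for depth or length. The submitters' processing notes name STAR 2.7.6, Salmon 1.4.0 and the GRCm38.p6 genome, without their roles or order. The annotation and the way transcripts were summed to genes are not given in the sources used here. Reads shared by close copies of a gene may have been divided between them by estimation, so values for such copies are uncertain.

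Groups and replicate numbers were taken from the sample titles. Between 7.92% and 8.93% of the deposited expected counts in a library were not whole, and all were rounded to whole numbers first. The libraries held 50424208, 42132308 and 43365369 reads for JH716-18, 42585278, 45336225 and 42574291 for LN1A, and 44061135, 46798625 and 46204759 for LN2A. The 20 genes with the most reads took 10.0 ± 0.145%, 7.97 ± 0.134% and 9.24 ± 0.162% of the reads of the 3 lines (SD, n = 3). No read was counted for 27190 symbols. Filtering with edgeR's filterByExpr left 15655 symbols, which held at least 99.953% of the reads of each library. Positions were taken from the GENCODE annotation of GRCm38 by symbol, and 97.9% of the tested symbols had a single position.

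Counts were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, R 4.3.3) in 1 fit over all 9 libraries without a block, for each pair of lines and for any difference among the 3. P-values were adjusted by Benjamini-Hochberg at 0.05, and fold changes are the first line named minus the second. Standard errors were taken as the size of the log2 fold change divided by the square root of F. The common biological coefficient of variation was 4.34%. Where a line had no read of a gene, the fold is a bound against a floor of 3 reads per library, and where it had 1 to 3 reads in all, the ratio is given with its exact binomial 95% counting interval.

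Before the data were examined, 30 gene lists were written, holding 650 genes of which 647 were in the table. Lists with at least 5 measured genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and 26 lists entered the adjustment. The neuroendocrine, fibroblast and endothelial lists had 4 measured genes each and the Y-linked list 0, so they were not tested. The 5 engineered loci, tested as a list, did not pass in any comparison (adjusted p = 0.510, 0.750 and 0.942). Neuroendocrine genes were called higher in 2 of 4 cases (3 adjusted over the list alone) in LN1A against JH716-18 and lower in 2 of 4 in LN2A against LN1A. The lists were also tested with an estimated correlation and with fry.

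The rule for the genes named in the text was fixed at the same time. It took, for each comparison, the 8 largest changes in each direction among genes with an adjusted p under 0.05, a mean log2 CPM of at least 2, a symbol that is not a predicted gene, and libraries that did not overlap. It added up to 4 members of each list described, with a mean log2 CPM of at least 0, the engineered loci in every library, and 5 genes per direction that changed the same way in both steps, under the same filters as the 8 and ranked by the smaller of the 2 changes. Members of a list that did not pass were allowed as examples with their values, and the text says where a gene was chosen after its values were seen.

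The fits were tested on simulated counts for the same 15655 genes, of which 200 were changed, 50 by each of 4 fold sizes. For LN1A against JH716-18, 56% of the 1.25-fold, 82% of the 1.5-fold, 76% of the 2-fold and 98% of the 4-fold changes were recovered. For LN2A against LN1A the shares were 66%, 72%, 76% and 94%, and for LN2A against JH716-18 they were 68%, 58%, 84% and 94%. Of 15455 unchanged genes, 6, 8 and 2 were called in these comparisons. Of 100 lists of unchanged genes, 3, 3 and 2 had a camera p under 0.05. Lists of genes that vary together were not simulated, so these counts do not give the error rate of camera for such lists. The estimated correlation within the gene lists tested ranged from -0.078 (engineered loci) to 0.364 (YAP and TAZ targets).

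Overlaps of calls between comparisons that share libraries were set beside those of 100 simulations of unchanged groups and beside those of independent lists of the same sizes. The alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter (28047 genes), a stricter filter (12386 genes with a CPM of at least 1 in every library of a line and a mean count of at least 50), a fit of only the 2 lines compared, the replicate number as a block, and leaving out each library in turn. Exon-level reads of the deleted loci were not analysed here.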

Results

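Messenger RNA was sequenced from 3 mouse lung squamous cell carcinoma cell lines that form a series of descent on a C57BL/6 background. JH716-18 is the parental line, LN1A was derived from it, and LN2A is a highly metastatic line derived from LN1A. The labels give all 3 lines one genotype, with high Sox2 and loss of p53, p16 and Pten. Each line had 3 libraries, so that 9 libraries were compared. The libraries held between 42132308 and 50424208 estimated reads assigned to genes, and 15655 gene symbols had enough reads to be tested. At this depth, 3 reads in a library correspond to between 0.0587 and 0.0705 CPM (reads scaled to library size), a limit that covers counting error only. The labels do not say whether the libraries of one line came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

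The genes named in the genotype were examined first. Sox2, the lineage transcription factor of squamous epithelium (chromosome 3, 34650405 to 34652461, GRCm38), was read at 319, 317 and 284 CPM in the JH716-18 libraries. It stood at 254, 253 and 232 CPM in LN1A and at 140, 139 and 131 CPM in LN2A. Sox2 was therefore lower in LN2A than in the parental line, with a log2 fold change of -1.17 ± 0.05 (SE, edgeR quasi-likelihood test, adjusted p = 1.23e-12). Trp53, which encodes p53 (chromosome 11, 69580359 to 69591873), had 67.8, 67.1 and 71.4 CPM in JH716-18, 72.4, 75.02 and 70.4 CPM in LN1A, and 58.6, 61.0 and 57.8 CPM in LN2A. Cdkn2a, which encodes p16 and p19Arf (chromosome 4, 89274471 to 89294653), had 48.2, 49.7 and 48.6 CPM in JH716-18, 66.5, 57.4 and 62.3 CPM in LN1A, and 70.5, 70.0 and 68.0 CPM in LN2A. Its neighbour Cdkn2b had 21.0, 21.0 and 21.2 CPM in JH716-18, 13.8, 13.3 and 13.9 CPM in LN1A, and 20.5, 22.4 and 19.8 CPM in LN2A. Pten (chromosome 19, 32757497 to 32826160) had 68.1, 70.1 and 72.2 CPM in JH716-18, 61.8, 58.6 and 64.5 CPM in LN1A, and 76.2, 72.5 and 79.7 CPM in LN2A. A count per gene does not show which exons were read, so these values do not check the deletions. Such a count also does not show whether Sox2 reads came from the position given or from an added copy.

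The 3 lines were separated along the first principal component, which held 64.0% of the variance of log2 CPM, and the second, which held 21.5%. Pearson's r across genes was 0.989 to 0.992 between libraries of one line. It was 0.966 to 0.968 between JH716-18 and LN1A, 0.937 to 0.942 between LN1A and LN2A, and 0.928 to 0.933 between JH716-18 and LN2A. Genes are not independent replicates. Of the 15655 genes, 12449 (79.5%) differed among the 3 lines at an adjusted p under 0.05 (edgeR). All pairs of libraries within a line differed by more than counting noise, so none was taken for a library deposited more than once. This does not show that they came from separate cultures.

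**Figure D1:**
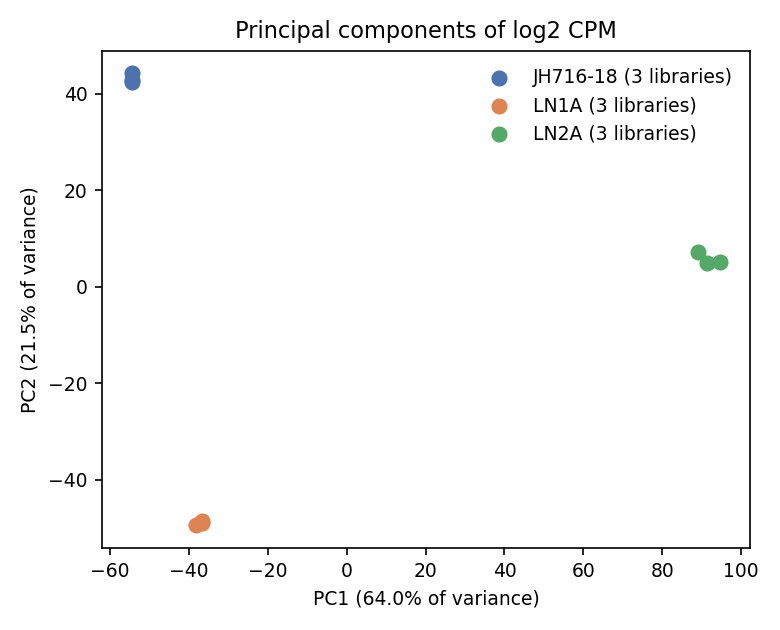
Principal components of log2 CPM over the genes tested, with 1 point per library and 3 libraries per line. PC1 (64.0% of variance) parts LN2A from JH716-18 and LN1A, and PC2 (21.5%) parts LN1A from JH716-18, with the 3 libraries of each line close together.

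The comparison of LN1A with JH716-18 shows what distinguished the first derivative from its parental line. Genes of adhesion to and degradation of the extracellular matrix rose, those of class I antigen presentation rose, and those of cholesterol synthesis fell. These list calls were lost with an estimated correlation (adjusted p = 0.0556, 0.0859 and 0.0556). Itga2, the collagen-binding integrin subunit alpha 2 (chromosome 13, 114833081 to 114932100), went from 4.49 ± 0.358 CPM in JH716-18 to 63.1 ± 1.99 CPM in LN1A (SD, n = 3), a log2 fold change of 3.80 ± 0.06 (SE, edgeR adjusted p = 5.33e-17). Mmp9, a matrix metalloproteinase that cleaves type IV collagen (chromosome 2, 164940780 to 164955850), went from 5.87 ± 0.0658 to 78.2 ± 3.10 CPM, a log2 fold change of 3.74 ± 0.06. Krt5, the type II keratin of basal squamous cells (chromosome 15, 101707070 to 101712898), fell to 24.7% of its parental CPM, with a log2 fold change of -2.02 ± 0.03 (SE). In all, 8810 genes changed (56.3% of those tested), 4378 higher and 4432 lower, and 1782 changed at least 2-fold, 909 higher and 873 lower. With a stricter filter on low counts, 938 changed at least 2-fold, 521 higher and 417 lower.

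Genes were ranked by size of change where they had a mean log2 CPM of at least 2, a symbol that is not a predicted gene, and no overlap between libraries. Beside Itga2 and Mmp9, the largest increases in LN1A by this rule were those of Fam167a (log2 fold change 5.03 ± 0.13), Mical2, an actin-oxidising monooxygenase (3.98 ± 0.08), the natriuretic peptide receptor gene Npr3 (3.82 ± 0.09), the inducible nitric oxide synthase gene Nos2 (3.73 ± 0.10) and the class I genes H2-Q7 (3.82 ± 0.04) and H2-Q6 (3.32 ± 0.06). H2-Q6 and H2-Q7 are close copies, so the division of reads between them is uncertain. The largest decreases by this rule were those of Lpin1, a phosphatidate phosphatase (-3.86 ± 0.11), the glutathione transferase gene Gstm1 (-2.94 ± 0.11), the carboxylesterase gene Ces1d (-2.88 ± 0.10), Sgpp2 (-2.78 ± 0.10), the acetyl-CoA synthetase gene Acss2 (-2.70 ± 0.09), Sncg (-2.63 ± 0.12), Reep1 (-2.57 ± 0.11) and Mfsd4a (-2.47 ± 0.07).

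Of 26 gene lists with at least 5 measured members, 16 passed camera with its preset correlation, 9 upward and 7 downward. None of the 16 held with an estimated correlation, and that p is given beside each list. The list of matrix remodelling and invasion rose, with 26 of 30 measured members higher and 1 lower (median log2 fold change 0.80, camera adjusted p = 1.29e-10, adjusted p = 0.0556 with an estimated correlation). Serpine1, the plasminogen activator inhibitor, rose by 2.71 ± 0.05 on the log2 scale and the fibronectin receptor subunit Itga5 by 1.87 ± 0.08. Of the mesenchymal list, 11 of 19 members rose and 2 fell (adjusted p = 0.00307; adjusted p = 0.135 with an estimated correlation), with Acta2 at 2.12 ± 0.06, Axl at 1.54 ± 0.05 and Fn1 at 1.03 ± 0.06. Of the YAP and TAZ targets, 14 of 16 rose and none fell (adjusted p = 1.99e-06; adjusted p = 0.179 with an estimated correlation), among them Ccn2 (1.79 ± 0.03) and Ccn1 (1.48 ± 0.04). Of the TGF-beta and BMP targets, 9 of 16 rose and 4 fell (adjusted p = 0.0184; adjusted p = 0.165 with an estimated correlation), with Id1 at 1.17 ± 0.06 and Itgb6 at 1.04 ± 0.04.

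Immune genes did not move in one direction in this first step. Of the class I presentation list, 18 of 22 members rose and 2 fell (median 0.74, adjusted p = 3.19e-07; adjusted p = 0.0859 with an estimated correlation), and its transcriptional activator Nlrc5 rose by 1.92 ± 0.05. Of the class II list, 7 of 8 rose (median 1.85, adjusted p = 0.00307; adjusted p = 0.0875 with an estimated correlation), with Cd74 at 2.14 ± 0.09. Of the chemokines, cytokines and NF-kB targets, 24 of 37 rose and 5 fell (adjusted p = 4.49e-05; adjusted p = 0.135 with an estimated correlation), led by Cxcl2 (3.68 ± 0.20), Csf2 (3.23 ± 0.07), Icam1 (2.54 ± 0.05) and Ccl2 (2.15 ± 0.05). Of the checkpoint and NK or T cell ligands, 16 of 23 rose and 3 fell (adjusted p = 0.000613; adjusted p = 0.0556 with an estimated correlation), with Icosl at 2.79 ± 0.16 and the NKG2D ligand gene Ulbp1 at 1.44 ± 0.04. The interferon response list went the other way, with 24 of 42 members lower and 8 higher, though by little (median -0.22, adjusted p = 0.0184; adjusted p = 0.253 with an estimated correlation). Rsad2 fell to a log2 fold change of -1.46 ± 0.06 and Stat1, the transcription factor of the interferon pathway, to -1.24 ± 0.04, whereas Zbp1 rose by 0.81 ± 0.07.

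Of the squamous terminal differentiation list, 21 of 26 members fell and 3 rose (median -0.74, adjusted p = 1.93e-06; adjusted p = 0.0997 with an estimated correlation). Krt4 fell to -3.46 ± 0.14, the desmoglein gene Dsg1b to -3.38 ± 0.23 and Krt13 to -2.19 ± 0.05, whereas Sprr2d, one of a family of similar genes whose reads may be shared, rose by 2.25 ± 0.19. Of the squamous and basal identity list, 16 of 26 fell and 5 rose (median -0.18, adjusted p = 0.00517; adjusted p = 0.295 with an estimated correlation). Krt15 fell to -3.53 ± 0.19 and Fgfbp1 to -1.22 ± 0.05, whereas Krt17 rose by 2.85 ± 0.04. The epithelial adhesion and polarity list did not pass (adjusted p = 0.745), with 13 of 29 members higher and 13 lower. Krt7 (1.81 ± 0.05) and Krt19 (1.47 ± 0.03) rose, and Ovol1 (-1.53 ± 0.09) and Tjp3 (-1.12 ± 0.07) fell.

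Of 22 cholesterol synthesis genes, 20 fell and 1 rose (median -1.34, adjusted p = 2.94e-12; adjusted p = 0.0556 with an estimated correlation). The lanosterol synthase gene Lss fell to -1.79 ± 0.04, Mvd to -1.78 ± 0.05, Acat2 to -1.75 ± 0.04 and Insig1 to -1.73 ± 0.04. Of 25 NRF2 and oxidative stress genes, 19 fell and 3 rose (median -0.34, adjusted p = 0.000337; adjusted p = 0.231 with an estimated correlation), with Nqo1 at -1.16 ± 0.05 and Akr1b8, which rose, at 1.97 ± 0.07. Of 22 genes of the integrated stress and unfolded protein responses, 13 fell and 6 rose (adjusted p = 0.0184; adjusted p = 0.231 with an estimated correlation), with Trib3 at -1.13 ± 0.04 and Sesn2 at -1.02 ± 0.04. Cell cycle genes rose slightly, 23 of 30 higher and 2 lower (median 0.23, adjusted p = 2.23e-05; adjusted p = 0.165 with an estimated correlation), none of them 2-fold, with Ccne1 at 0.78 ± 0.05 and Mybl2 at 0.75 ± 0.04. The mitochondrial transcripts, kept as a sign of RNA quality, fell in 10 of 13 cases (adjusted p = 0.00352; adjusted p = 0.231 with an estimated correlation), and their share of reads was 4.31 ± 0.0939% in JH716-18 and 3.22 ± 0.115% in LN1A (SD, n = 3).

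The median of the immune cell markers was 0.140 CPM in JH716-18 and 0.153 CPM in LN1A, that of the endothelial markers 0.0329 and 0.0540 CPM, and that of the fibroblast markers 0.0130 and 0.0155 CPM. The immune marker list did not pass camera (adjusted p = 0.368), and its highest member was Cd14, at 11.5 ± 0.780 CPM in JH716-18 and 15.3 ± 0.349 CPM in LN1A (log2 fold change 0.40 ± 0.07). Csf1r, the receptor of a macrophage growth factor, rose from 0.126 ± 0.0439 to 1.29 ± 0.106 CPM. Of the fibroblast markers, Pdgfrl had 20.1 ± 0.429 CPM in JH716-18 and 20.5 ± 1.55 CPM in LN1A, and Pdgfra rose from 0.710 ± 0.131 to 2.50 ± 0.312 CPM. Csf1r and Pdgfrl were chosen after their values were seen. Adjusted over the list alone, 28 rather than 27 matrix genes, 21 rather than 20 class I genes, 33 rather than 32 interferon genes, 23 rather than 22 NRF2 genes, 3 rather than 2 endothelial markers and 3 rather than 2 neuroendocrine genes were called.

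**Figure D2:**
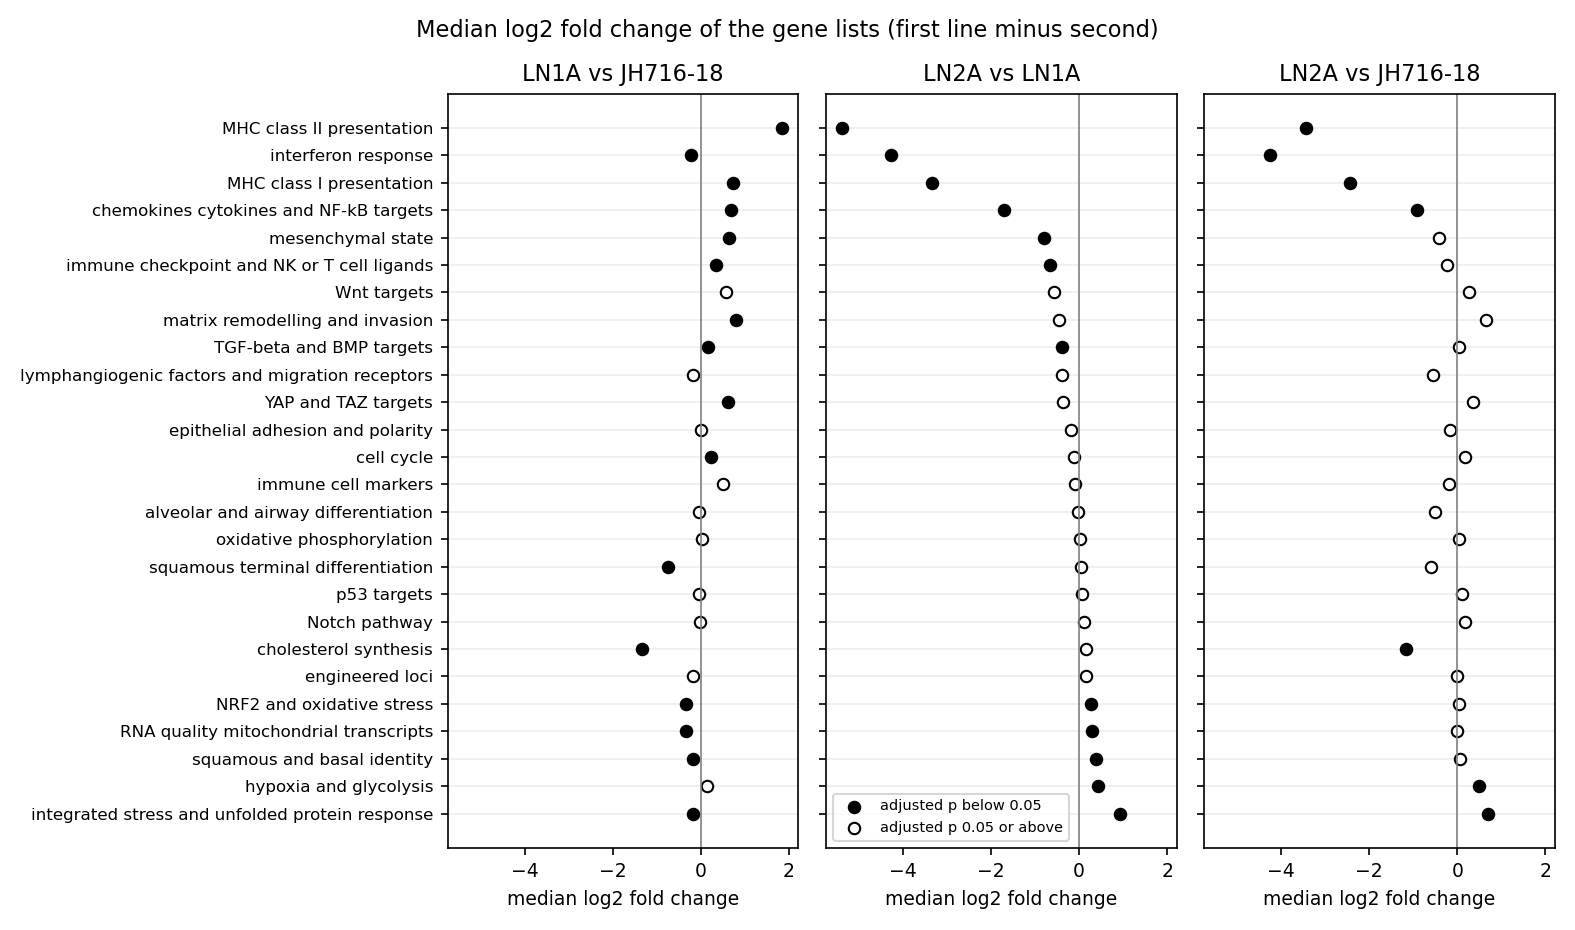
Median log2 fold change of each of 26 gene lists in the 3 comparisons (panels, first line minus second), with genes without reads in one line set to their bound; filled points passed camera with its preset correlation at an adjusted p under 0.05. The interferon response list lies at -0.22 in LN1A against JH716-18 and at -4.26 in LN2A against LN1A.

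The comparison of LN2A with LN1A shows what set the highly metastatic line apart from the line it was derived from. With a single line at each stage of descent, no difference can be tied to metastatic ability rather than to other differences between the lines. Genes of the interferon response and of antigen presentation fell in LN2A, several of them to almost no reads, and genes of the integrated stress and unfolded protein responses rose. Oas1a, an interferon-induced RNA sensor (chromosome 5, 120896256 to 120907521), went from 53.4 ± 0.753 CPM in LN1A to 0.0801 ± 0.0810 CPM in LN2A (SD, n = 3), a log2 fold change of -9.31 ± 0.13 (SE, edgeR adjusted p = 1.28e-18). H2-Q7 (chromosome 17, 35439155 to 35443773) had 746 ± 5.80 CPM in LN1A and no read in any LN2A library, at least 11226-fold lower against a floor of 3 reads per library. Xist, the non-coding RNA of X inactivation (X chromosome, 103460366 to 103483254), went from 924 ± 40.8 CPM to 0.406 ± 0.124 CPM, a log2 fold change of -11.14 ± 0.08. In all, 10143 genes changed (64.8% of those tested), 5062 higher and 5081 lower. Of the 2582 that changed at least 2-fold, 750 were higher and 1832 (71.0%) lower. With the stricter filter, 1539 changed at least 2-fold, 409 higher and 1130 lower.

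By the same rule, the largest increases in LN2A over LN1A were those of Sncg (log2 fold change 4.99 ± 0.10), the protocadherin gene Pcdh7 (4.86 ± 0.08), Spink5, an inhibitor of epidermal serine proteases (4.60 ± 0.05), Pdzd7 (4.48 ± 0.11), the transcription factor gene Sox6 (4.01 ± 0.08), the guidance receptor gene Robo2 (3.51 ± 0.07), Tmem154 (3.27 ± 0.07) and the water and glycerol channel gene Aqp3 (3.25 ± 0.09). The largest decreases by that rule, beside those of H2-Q7, Xist and Oas1a, were those of H2-Q6, the immunoproteasome gene Psmb8 (-9.06 ± 0.08), Rtp4 (-9.03 ± 0.12), Apol9a (-8.61 ± 0.10) and the peptide transporter gene Tap1 (-8.46 ± 0.13). H2-Q6 had 1 read over the 3 LN2A libraries against 318 ± 5.86 CPM in LN1A, a ratio of 43073 whose counting interval starts at 7730. Apol9a has a near-identical neighbour, so its counts are uncertain.

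Of the 26 lists, 12 passed camera with its preset correlation, 5 upward and 7 downward, and 6 of the 12 held with an estimated correlation. All 42 interferon response genes fell, 41 of them at least 2-fold (median log2 fold change -4.47, or -4.26 with genes without reads set to their bound, camera adjusted p = 3.65e-22, adjusted p = 0.0153 with an estimated correlation). Ifi27l2a had 14.1 ± 0.628 CPM in LN1A and no read in LN2A, at least 212-fold lower. The antiviral GTPase gene Mx2 had 8.51 ± 0.521 CPM in LN1A and 3 reads over the 3 LN2A libraries, a ratio of 385 whose counting interval starts at 131. Of the class I presentation list, 18 of 22 members fell, each at least 2-fold, and 3 rose (median -3.33, adjusted p = 8.68e-10, adjusted p = 0.0310 with an estimated correlation). Psmb9, of the immunoproteasome, was at least 471-fold lower. The 3 that rose, named after their values were seen, were the endoplasmic reticulum chaperone genes Calr (0.45), Canx (0.63) and Pdia3 (0.30), which also serve other proteins. All 8 class II genes fell at least 2-fold (median -5.39, adjusted p = 0.000287, adjusted p = 0.0310 with an estimated correlation), with Cd74 at -5.60 ± 0.13.

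Of the chemokines, cytokines and NF-kB targets, 31 of 37 fell and none rose (median -1.70, adjusted p = 1.6e-10, adjusted p = 0.0310 with an estimated correlation). Csf2, which encodes the cytokine GM-CSF, fell to -4.84 ± 0.08, Tnf to -4.11 ± 0.10, Cxcl10 to -3.92 ± 0.09 and Tgfb2 to -3.61 ± 0.08. Of the checkpoint and NK or T cell ligands, 17 of 23 fell and 3 rose (median -0.67, adjusted p = 0.0011, adjusted p = 0.0310 with an estimated correlation), with Tnfsf10 at -5.52 ± 0.27 and Lgals9 at -2.81 ± 0.05. Markers of immune cells did not pass (adjusted p = 0.551). Their median was 0.153 CPM in LN1A and 0.0878 CPM in LN2A, and Cd14 fell from 15.3 ± 0.349 to 5.51 ± 0.213 CPM. The endothelial markers had a median of 0.0540 CPM in LN1A and 0.0706 CPM in LN2A, and the fibroblast markers 0.0155 and 0.0146 CPM. Pdgfra rose to 6.01 ± 0.646 CPM in LN2A, Pdgfrl fell to 8.25 ± 0.928 CPM, and Csf1r, chosen after its values were seen, fell to 0.258 ± 0.0531 CPM.

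**Figure D3:**
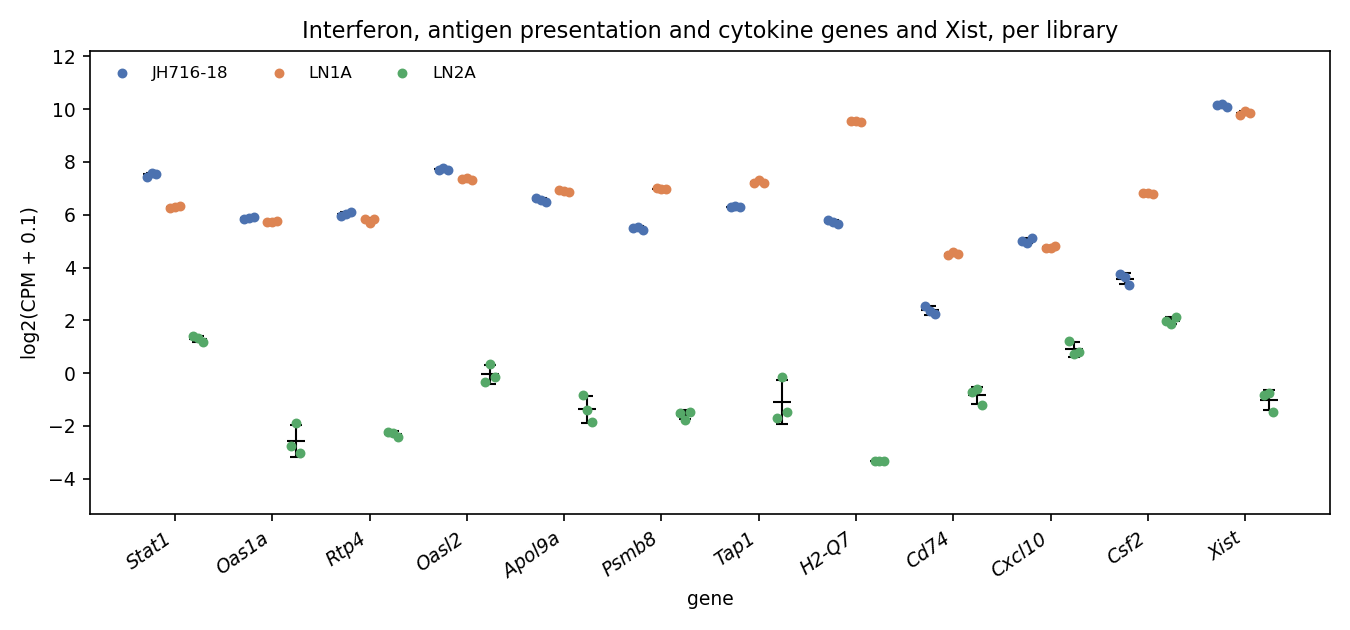
CPM per library on a log2 scale, after adding 0.1 CPM, for genes of the interferon response, antigen presentation and cytokines and for Xist, with 1 point per library, 3 libraries per line, and black bars for their mean ± SD. Each of the 12 genes is lower in every LN2A library than in every library of the other lines, and H2-Q7 has no read in LN2A.

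All 22 genes of the integrated stress and unfolded protein responses rose in LN2A, 11 of them at least 2-fold (median 0.94, adjusted p = 1.28e-12, adjusted p = 0.0216 with an estimated correlation). Atf3 rose by 2.24 ± 0.07, Ddit3, which encodes CHOP, by 2.12 ± 0.07, Trib3 by 1.75 ± 0.04 and Xbp1 by 1.68 ± 0.04. Hypoxia and glycolysis genes rose in 19 of 27 cases and fell in 5 (median 0.43, adjusted p = 0.000437; adjusted p = 0.157 with an estimated correlation), with the oxidoreductase gene Ero1l at 1.60 ± 0.03 and Ndrg1 at 1.02 ± 0.03, whereas Egln3 fell to -1.26 ± 0.04. NRF2 and oxidative stress genes rose in 17 of 25 cases and fell in 5 (adjusted p = 0.00408; adjusted p = 0.391 with an estimated correlation), with Gclc, a subunit of the first enzyme of glutathione synthesis, at 2.03 ± 0.04 and Aldh3a1 at 1.54 ± 0.04. Of the mitochondrial transcripts, 10 of 13 rose (adjusted p = 0.0147; adjusted p = 0.391 with an estimated correlation), and their share of reads was 3.999 ± 0.0962% in LN2A.

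Of the mesenchymal list, 11 of 19 members fell and 2 rose (median -0.80, adjusted p = 0.00408; adjusted p = 0.149 with an estimated correlation), with Sparc at -3.62 ± 0.05 and Fn1, fibronectin, at -2.52 ± 0.06. Of the TGF-beta and BMP targets, 13 of 16 fell and 1 rose (median -0.39, adjusted p = 0.00167; adjusted p = 0.0771 with an estimated correlation), with Ltbp2 at -1.84 ± 0.06 and Ccn2 at -1.16 ± 0.03. The matrix remodelling list did not pass (adjusted p = 0.0613), with 17 of 30 members lower and 9 higher. Mmp9 fell to 5.81% and Itga2 to 7.06% of their LN1A CPM, with log2 fold changes of -4.10 ± 0.06 and -3.82 ± 0.06. Of the squamous and basal identity list, 17 of 26 rose and 4 fell (median 0.38, adjusted p = 0.00408; adjusted p = 0.391 with an estimated correlation). Krt5 rose by 1.54 ± 0.03 and Fgfbp1 by 1.36 ± 0.05, whereas the homeobox gene Pitx1 fell to -1.85 ± 0.04 and the P-cadherin gene Cdh3 to -1.35 ± 0.04.

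The epithelial adhesion list (8 of 29 higher, 17 lower, adjusted p = 0.086), the cell cycle list (8 of 30 higher, 16 lower, adjusted p = 0.248) and the terminal differentiation list (12 of 26 higher, 7 lower, adjusted p = 0.257) did not pass in this comparison. Among their members, Ovol1 (1.38 ± 0.09) and Dsg1b (6.51 ± 0.17) rose, and Cldn1 (-1.23 ± 0.08), Krt18 (-1.14 ± 0.05) and Ccne1 (-1.04 ± 0.05) fell. The alveolar and airway list did not pass either (adjusted p = 0.604). Its member Nkx2-1, the lung lineage transcription factor (chromosome 12, 56531958 to 56536908), had 24.2 ± 1.11 CPM in JH716-18, 24.3 ± 0.475 CPM in LN1A and no read in LN2A, at least 366-fold lower than in LN1A. Adjusted over the list alone, 32 rather than 31 chemokine genes, 26 rather than 25 epithelial genes and 20 rather than 19 terminal differentiation genes were called, and the other lists named here kept their counts.

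**Figure D4:**
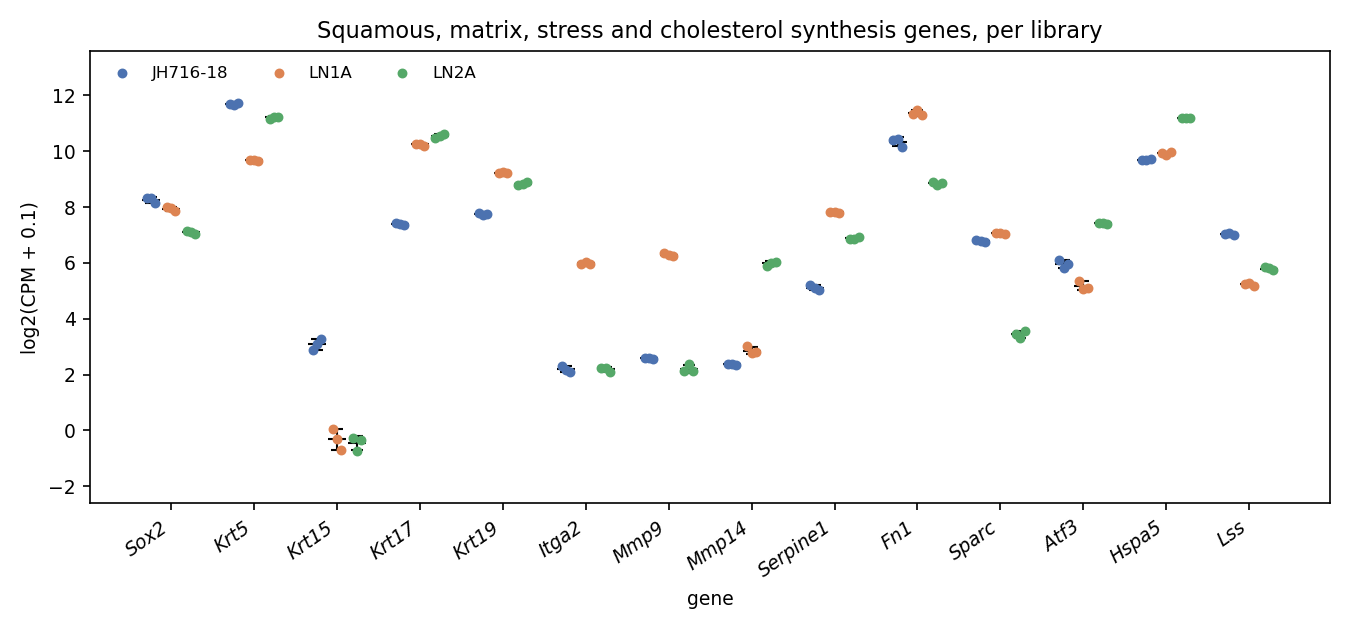
CPM per library on a log2 scale, after adding 0.1 CPM, for squamous, matrix, stress response and cholesterol synthesis genes, with 1 point per library, 3 libraries per line, and black bars for their mean ± SD. Itga2 and Mmp9 are high in LN1A alone, Mmp14 is high in LN2A alone, and Sox2 steps down from JH716-18 to LN1A to LN2A.

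The comparison of LN2A with JH716-18 gives the sum of both steps. Interferon response genes fell and stress response genes rose against the parental line as well, and both calls held with an estimated correlation. Class I and cholesterol synthesis genes also fell with the preset correlation, but not with an estimated one (adjusted p = 0.0711 and 0.0534 with an estimated correlation). Fbp2, a fructose bisphosphatase (chromosome 13, 62836877 to 62858422), had the largest increase by that rule, from 0.947 ± 0.287 CPM in JH716-18 to 58.2 ± 0.870 CPM in LN2A (SD, n = 3), a log2 fold change of 5.94 ± 0.09 (SE, edgeR adjusted p = 3.73e-18). Mmp14, the membrane-bound metalloproteinase, rose from 5.05 ± 0.0773 to 63.0 ± 3.18 CPM (3.64 ± 0.07). In all, 10646 genes changed (68.0%), 5136 higher and 5510 lower, and 2875 changed at least 2-fold, 910 higher and 1965 lower. With the stricter filter, 1713 changed at least 2-fold, 543 higher and 1170 lower.

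By that rule, the other genes with the largest increases in LN2A over the parental line were St3gal6 (4.86 ± 0.12), Nat8l (4.74 ± 0.06), the collagen receptor gene Ddr2 (4.53 ± 0.06), Pcdh7 (4.30 ± 0.08), the calcium sensor gene Ncs1 (4.15 ± 0.07), Soga1 (3.65 ± 0.14) and the stress cytokine gene Gdf15 (3.64 ± 0.10). By it, those with the largest decreases were H2-Q7 (at least 794-fold lower), H2-Q6, Xist (-11.43 ± 0.08), Oas1a (-9.46 ± 0.13), Rtp4 (-9.27 ± 0.12), Arhgap31 (-8.64 ± 0.11), Apol9a (-8.27 ± 0.10) and Oasl2 (-7.88 ± 0.08).

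Of the 26 lists, 7 passed camera, 2 upward and 5 downward, and 2 of the 7 held with an estimated correlation. All 42 interferon response genes were lower, each at least 2-fold (median -4.58, or -4.25 with genes without reads at their bound, adjusted p = 1.23e-20, adjusted p = 0.0185 with an estimated correlation). All 22 stress response genes were higher (median 0.70, adjusted p = 2.04e-10, adjusted p = 0.0355 with an estimated correlation), with Xbp1 at 1.65 ± 0.04, Atf3 at 1.45 ± 0.07 and the chaperone gene Hspa5 at 2355 ± 4.95 CPM in LN2A against 833 ± 15.9 CPM in JH716-18. Of the class I list, 18 of 22 fell and 3 rose (median -2.43, adjusted p = 5.68e-08; adjusted p = 0.0711 with an estimated correlation), and all 8 class II genes fell (median -3.43, adjusted p = 0.00388; adjusted p = 0.0809 with an estimated correlation). Of the chemokines and cytokines, 25 of 37 fell and 5 rose (median -0.91, adjusted p = 0.000991; adjusted p = 0.242 with an estimated correlation), with Cxcl10 at -4.17 ± 0.09 and Tgfb3 at -3.39 ± 0.08. Of the cholesterol synthesis genes, 20 of 22 fell and 1 rose (median -1.17, adjusted p = 1.42e-08; adjusted p = 0.0534 with an estimated correlation), with Mvd at -2.03 ± 0.05, Fdps at -1.71 ± 0.04 and Hmgcs1 at -1.57 ± 0.03. Of the hypoxia and glycolysis genes, 20 of 27 rose and 5 fell (median 0.49, adjusted p = 0.000252; adjusted p = 0.203 with an estimated correlation), with Adm at 1.90 ± 0.06.

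The squamous and basal identity list was divided, with 12 of 26 members higher and 11 lower (adjusted p = 0.942, median 0.07, mean -0.05). Krt15 (-3.72 ± 0.20) and Pitx1 (-1.90 ± 0.04) were lower and Krt17 (3.14 ± 0.04) was higher. The mesenchymal list (7 of 19 higher, 6 lower, adjusted p = 0.774), the epithelial list (7 of 29 higher, 15 lower, adjusted p = 0.335), the cell cycle list (18 of 30 higher, 7 lower, adjusted p = 0.0939) and the checkpoint ligands (8 of 23 higher, 12 lower, adjusted p = 0.663) did not pass. The matrix remodelling list stood at the threshold (16 of 30 higher, 9 lower, adjusted p = 0.05002; adjusted p = 0.427 with an estimated correlation) and is not counted among the 7. Of their members, Sparc (-3.34 ± 0.05), Tjp3 (-2.38 ± 0.08), Vim (-0.99 ± 0.04) and Tnfsf10 (-5.04 ± 0.28) fell, and Krt7 (2.55 ± 0.05), Rrm2 (1.06 ± 0.03) and Tnfsf18 (4.05 ± 0.22) rose. Immune cell markers did not pass (adjusted p = 0.942), with Cd14 at -1.07 ± 0.07. Adjusted over the list alone, the counts of these lists were the same.

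Several lists passed camera in none of the 3 comparisons. Of 23 lymphangiogenic factors and migration receptors, 8 were higher and 11 lower (adjusted p = 0.745) in LN1A against JH716-18, 8 higher and 13 lower (adjusted p = 0.265) in LN2A against LN1A and 5 higher and 15 lower (adjusted p = 0.170) in LN2A against JH716-18. Of 20 p53 targets, 7 were higher and 8 lower (adjusted p = 0.745) in LN1A against JH716-18, 10 higher and 8 lower (adjusted p = 0.401) in LN2A against LN1A and 10 higher and 6 lower (adjusted p = 0.473) in LN2A against JH716-18. Of 10 Wnt targets, 6 were higher and 2 lower (adjusted p = 0.0752) in LN1A against JH716-18, 2 higher and 7 lower (adjusted p = 0.147) in LN2A against LN1A and 5 higher and 3 lower (adjusted p = 0.637) in LN2A against JH716-18. Of 12 Notch pathway genes, 5 were higher and 5 lower (adjusted p = 0.745) in LN1A against JH716-18, 5 higher and 4 lower (adjusted p = 0.604) in LN2A against LN1A and 7 higher and 4 lower (adjusted p = 0.425) in LN2A against JH716-18. Of 26 oxidative phosphorylation genes, 4 were higher and 7 lower (adjusted p = 0.651) in LN1A against JH716-18, 7 higher and 7 lower (adjusted p = 0.728) in LN2A against LN1A and 11 higher and 8 lower (adjusted p = 0.942) in LN2A against JH716-18. Of 11 alveolar and airway genes, 2 were higher and 5 lower (adjusted p = 0.368) in LN1A against JH716-18, 3 higher and 4 lower (adjusted p = 0.604) in LN2A against LN1A and 2 higher and 8 lower (adjusted p = 0.0939) in LN2A against JH716-18. The median of the oxidative phosphorylation list was positive and its mean negative in each comparison, and its test pointed down in LN1A against JH716-18 and up in the others. For the NRF2 list in LN2A against JH716-18 (9 of 25 higher, 8 lower, camera adjusted p = 0.663) the median was 0.03 and the mean -0.08. The median and mean also differed in sign for the Notch list in both steps and for the Wnt list and immune cell markers in LN2A against JH716-18. For the p53 targets in LN1A against JH716-18 they were both positive, at 0.04 and 0.05, while the test pointed down. That median was -0.04 with genes without reads set to their bound.

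Both derived lines were compared with the same parental libraries. Against JH716-18, 2520 genes were higher in both LN1A and LN2A, where independent lists of these sizes would share 1436, and 2698 were lower in both, where 1560 would be shared. In 100 simulations of all 9 libraries, with no gene changed in any line, none was shared. Almost no gene can pass the adjustment there, so that result does not bear on the observed overlap. The fold changes of the 2 derived lines had a Pearson's r of 0.428 across genes, and the median in the simulations was 0.496. With no gene changed, the shared parental libraries alone set the simulated r, so it is no reference for r among changed genes. The covariance was 0.524, against 0.0226 in the simulations, a difference of 0.501. The 3 parental libraries were not split between the derived lines, so part of the excess may come from sharing them.

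Genes called in both steps were counted by direction. From JH716-18 to LN1A and on to LN2A, 1265 genes rose in both steps (1416 expected of independent lists) and 1202 fell in both (1438 expected). More genes went up and then down (2200, against 1421 expected) or down and then up (1936, against 1433 expected). The LN1A libraries enter both steps, which favours opposite signs. In simulated unchanged groups no gene was called in both, but no gene was changed there, so this is no measure of the overlap between changed lists. Pearson's r of the fold changes of the 2 steps across genes was -0.186, against a median of -0.504 (-0.536 to -0.478) in the simulated unchanged groups. The shared LN1A libraries alone set the simulated r, so it is no reference for r among changed genes either. Among genes that changed at least 2-fold in each step, 98 rose in both (43.5 expected) and 202 fell in both (102 expected), while 469 rose and then fell (106 expected) and 186 fell and then rose (41.8 expected). Each pattern exceeded its expected number, which takes all tested genes as equally likely to change 2-fold. The excess alone is therefore no measure of stepwise change or of reversal. Genes that changed the same way in both steps were ranked by the smaller of the 2 changes, among those that met the rule above, with a mean log2 CPM of at least 2. The 5 with the largest increases were Fbp2 (3.04 ± 0.12, then 2.90 ± 0.07), Nat8l (2.18 ± 0.08, then 2.57 ± 0.05), Ncs1 (2.07 ± 0.09, then 2.08 ± 0.06), Ddr2 (2.01 ± 0.07, then 2.52 ± 0.05) and St3gal6 (2.88 ± 0.14, then 1.98 ± 0.09). The 5 with the largest decreases, ranked likewise, were Reep1 (-2.57 ± 0.11, then -2.16 ± 0.17), Cep85l (-1.93 ± 0.11, then -2.14 ± 0.16), Mark1 (-1.76 ± 0.07, then -1.93 ± 0.10), Stox2 (-1.76 ± 0.07, then -3.32 ± 0.12) and Spats2l (-1.73 ± 0.07, then -2.08 ± 0.10).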

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

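All alternatives were chosen before the data were examined. Of the counts of genes and lists and the correlation of fold changes, 175 values stayed within 1.5 times the reported count, or, for the correlation, on the same side of the highest simulated value of 0.527, and 9 moved. Any positive correlation below 0.527 would have met that criterion, so it says little about how stable the correlation is. The correlation was 0.385 with the stricter filter, against 0.428 as reported and 0.421 to 0.460 with 1 library left out. With the stricter filter, which tested 12386 genes, the genes changed at least 2-fold numbered 938 (521 higher, 417 lower) in LN1A against JH716-18, 1539 (409 higher, 1130 lower) in LN2A against LN1A, and 1713 (543 higher, 1170 lower) in LN2A against JH716-18, since fewer low genes were tested. With an estimated correlation 0, 6 and 2 lists passed in these comparisons, and with fry, which does not compare a list with other genes, 25, 23 and 25 passed. With fry the lymphangiogenic list in LN1A against JH716-18 (adjusted p = 0.0134) and the oxidative phosphorylation list in LN2A against JH716-18 (adjusted p = 0.0474) turned direction; the cause was not tested. Of the values of named genes, 6078 kept their direction and side of the threshold and 25 lost the call, those of mt-Co2, mt-Atp6, mt-Co3, mt-Nd2, Egfl7 and Pten. Of the adjusted p of single lists, 1019 kept their side, 41 came to pass, 27 ceased to pass and 2 turned.

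Leaving out each library in turn gave 8054 to 8999, 9587 to 10256 and 10072 to 10785 genes changed in the 3 comparisons, and 12118 to 12356 differing among the lines. Genes changed at least 2-fold numbered 1705 to 1891, 2550 to 2668 and 2875 to 2991, and lists passing 16, 12 and 7 to 8. No scaling moved the median of all genes by over 0.1. The replicate numbers paired the samples at most in part, with r between -0.06 and 0.33 for the deviations of libraries with one number. Replicates 2 and 3, but not 1, correlated best with their own number in each comparison. A batch shared by replicate number can therefore not be excluded. With the replicate block 8973, 10275 and 10777 genes changed, 12525 differed among the lines, and 16, 12 and 7 lists passed. Depth limits genes near 3 reads per library, where only bounds are given. The alternatives for normalised units were not run, since the table holds counts.

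The 6 libraries of 2 lines make 10 splits, too few for a share under 0.05. The real split gave 8810, 10143 and 10646 genes changed, where the highest other split gave 1, 0 and 0, and 1782, 2582 and 2875 genes changed at least 2-fold, where the highest other gave 1, 0 and 0. Lists passing numbered 16, 12 and 7, where the highest other split gave 12, 13 and 7, so that 1, 2 and 5 of the 10 splits gave as many. For the difference among the 3 lines, 1 of 100 splits, the real one, gave 12449 genes and the highest other gave 5863. This argues against a random grouping of these libraries only. The other splits mix lines within a group, and libraries of a line may be technical, so chance differences between cultures are not excluded.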

Other observations

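The gene families and the genes without reads in this part were chosen after their values were seen, as was the test of Y-linked reads, and the other tests were chosen before. The limits written beforehand did not include the random sets used for genes of the X chromosome. In LN2A, 33 genes had at most 3 reads in every library while both other lines had a mean of at least 2 CPM, against 0 such genes for LN1A and 2 for JH716-18. A gene that went off in LN1A and stayed off in LN2A could not meet this rule, so these counts do not compare the steps. The 33 genes lay on 15 chromosomes. Of them, 6 were on 4 immune lists written beforehand, those of the interferon response, class I, class II, and chemokines and cytokines. The other 27 include interferon-induced and MHC genes that those lists lack, such as H2-Q5, Gbp5, Gbp6, Ifi47, Tgtp1, Tgtp2, Sp100 and Trim34b, so the lists do not part immune from other genes here. Nkx2-1 and its neighbour Sfta3-ps (chromosome 12, 56488321 to 56529427) both had no read. The teneurin gene Tenm3 went from 26.3 ± 0.608 CPM in JH716-18 and 16.7 ± 1.19 CPM in LN1A to no read, and Tfap2c, a transcription factor gene, from 26.9 ± 1.78 and 2.83 ± 0.199 CPM to no read (SD, n = 3).

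Of 20 cytosolic aminoacyl-tRNA synthetase genes, 15 rose and 2 fell in LN2A against LN1A (median log2 fold change 0.36), with Wars at 1.17 ± 0.04, Eprs at 0.88 ± 0.03 and Kars at -0.61 ± 0.03 (SE, edgeR). In LN1A against JH716-18, 3 rose and 12 fell. Of 9 HoxA genes, 6 fell in each step and none rose, with Hoxa2 at -2.48 ± 0.12 in LN2A against LN1A. Of 5 insulin-like growth factor binding protein genes, 4 fell and 1 rose in each step: Igfbp7 rose by 2.51 ± 0.12 and then fell to -6.70 ± 0.20, and Igfbp3 went from -0.22 ± 0.03 to 0.18 ± 0.03. Of 7 laminin chain genes, Lamb3 (0.88 ± 0.04) and Lama3 (0.60 ± 0.04) rose and Lamc2 (-0.67 ± 0.04) and Lamb1 (-0.69 ± 0.04) fell in LN2A against LN1A. The directions of these named genes held under TMM, RLE, upper-quartile and no scaling.

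The fall of all 42 interferon response genes from LN1A to LN2A was set against 4 explanations. Loss of the MHC segment of chromosome 17 was argued against by position alone, since 41 members lie elsewhere, on 15 chromosomes, with a median log2 fold change of -4.58. At most 1 member could have been lost with that segment. Whether the segment itself was lost, with genes such as H2-Q6, H2-Q7 and Psmb9, was not tested. RNA of immune, endothelial or fibroblast cells in LN1A was argued against by their 40 markers, with a median of 0.0540 CPM where the interferon genes had 44.7 CPM, and scaling by the list's median, at most -4.47 under 4 scalings. Near-complete loss of the RNA of a single receptor or kinase was argued against by the lowest of 7 such genes, Ifnar2, at -0.86. Ifngr2 (-0.77), Ifngr1 (-0.70), Jak2 (-0.46) and Ifnar1 (-0.20) were called lower too, Jak1 (0.13) was higher and Tyk2 was not called. A joint partial fall of these genes therefore stays open. A change in Stat1, a list member that fell from 77.9 to 2.37 CPM, stays open, as does one in the members Stat2 or Irf9, which fell too. Sequence changes were not tested here.

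Xist fell to 0.406 CPM in LN2A, with 12 to 23 reads per library. Reactivation of the inactive X chromosome was argued against by X-linked genes, whose median differed from the autosomal one by 0.0446 (95% interval -0.00262 to 0.0721). A male source that kept its Y chromosome was argued against by 0 reads of Y-linked genes in any LN2A library. The values met the limits written beforehand for loss of the inactive X chromosome. In LN2A against LN1A, 4 genes that escape inactivation had a median -0.216 relative to other X-linked genes, whose own median lay close to the autosomal one. However, 10.9% of random sets of X-linked genes lay as low, a comparison that those limits did not include. Loss of the inactive X chromosome can therefore not be told apart from its presence. The neighbours Jpx (0.68 ± 0.13) and Ftx (0.44 ± 0.06) rose.

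Runs of neighbouring genes shifted together. In LN2A against LN1A the median log2 fold change was -0.42 on chromosome 8, with all 17 windows of 50 genes past the threshold, and 0.39 on chromosome 5, with 19 of 20; in LN1A against JH716-18 it was -0.30 on chromosome 1 and -0.23 on chromosome 17 (permutation p = 0.0001 each, the smallest that 10000 random sets of genes can give). GC content and gene length were argued against, since 245 windows passed the threshold over the 3 comparisons both before and after removing their trend, a ratio of 1, and 47, 85 and 97 of the 52, 93 and 100 passed both times. The higher and the lower expressed genes of chromosome 8, parted at the middle, shifted by -0.42 and -0.43, a difference of 0.0192. A copy number difference would give this, but so would any other even shift. Only chromosome 8, which had the largest median shift in LN2A against LN1A, was divided in this way. As a hypothesis, the lines may differ in copy number of whole chromosomes or parts of them, which was not measured in DNA here.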
